A study of Mus musculus with 12 samples.

How the data were processed

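Total RNA from 12 mouse oral tumours was measured on single-colour Illumina MouseRef-8 v2 bead arrays, 1 array per tumour. Per the labels' protocols, tumours grew for 21 days, were frozen in Trizol after isolation, and gave DNase-treated RNA that was turned into biotin-labelled cRNA. The submitters' processing notes name GenomeStudio and Partek without versions or roles. Other steps, and the version of any tool used before deposit, are not given in the sources used here.

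The authors deposited a table with 4 columns per array. Its signal column holds the mean bead intensity of each probe, not normalized between arrays, per the file headers and the differing array medians. Its detection p-value, per the file headers, sets each probe against the array's background. The number of beads behind each probe and their standard error are 2 other measures the authors deposited, and neither entered a test between the tumour types. A second deposited table holds the authors' processed intensity for the same arrays. Its values include negative ones and have nearly the same distribution on every array, with column medians from 16.4 to 16.7. Within each array they rank the probes as the scanner signals do, with a Spearman correlation of 1. Those values were read as linear, background-subtracted intensities, and they served only as an alternative.

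The array carries 25697 probes. The platform annotation gave 1 gene for 23978 probes, several for 0, and did not list 1719, which are unnamed here. Current symbols were looked up through the Entrez identifier, which matched for 23962 probes. The files name no genome build, so no coordinates are printed. Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values, an offset of 16 and quantile normalization to log2 values. A probe was kept when its detection p was under 0.05 on at least 6 of the 12 arrays. This left 11721 probes, 11044 of them with a gene. For each gene the probe with the highest mean over all arrays was used, which gave 8420 genes, 1990 of which had more than 1 kept probe. A gene not above background on any array of a group has a bound in place of a fold. The bound is the mean of the brighter group set against the mean over the dim group's arrays of the higher of 2 values, the probe's own and the lowest among probes detected on that array. Between 43.6% and 48.1% of probes were detected per array, and the number of arrays limits the precision.

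The groups were read from the labels: 6 KHR tumours and 6 KHR-NICD tumours, numbered 1 to 6 in each. The single comparison was KHR-NICD minus KHR, fitted with lmFit and eBayes of limma, with no block, and Benjamini-Hochberg adjustment at 0.05. Before the data were examined, 33 gene lists were fixed, 19 of pathways or epithelial states and 14 of cell type markers. The 26 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and limma's fry were alternatives. Lists with fewer measured members were left out of these tests. Each list also had a score per tumour, the mean log2 value of its measured members, compared by an exact two-sided permutation test. With 6 tumours against 6 the smallest such p is 0.0022, and 0.0563 is the smallest adjusted value if 1 list alone reaches it.

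Genes were named by a rule fixed in advance. It took Notch1 and the first 10 members of the Notch target list, the 10 largest rises and 10 largest falls past the threshold, and up to 4 members per list by smallest p, leaving predicted or clone-named genes out of the rises and falls. Fewer than 10 genes passed in each direction, so all were used. Genes named outside the rule are marked as chosen after their values were seen.

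The fit was tested on simulated data for this comparison, with 8420 genes of which 200 were changed, in 10 simulations. With residuals drawn from the tumours, it recovered 39.6% of genes changed by 0.5 on the log2 scale, 76.4% at 0.75, 92% at 1 and 97.4% at 1.5. In 10 separate draws from the same residuals, only the list of RAS-MAPK feedback and immediate early genes was lowered, by 0.4. The preset and the estimated correlation each recovered it in 10 of 10. Its estimated correlation in the tumours was low, at 0.00682, so recovery of lists with more correlated members was not tested. The preset correlation also called 1.7 unchanged lists per simulation among 25, against 0.1 with the estimated correlation.

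The alternatives were the deposited processed values, other background corrections, median centring, other probe filters, the mean of a gene's probes, other variance models, array weights, a replicate block, other thresholds and leaving out each tumour. Alternatives chosen after seeing the data were detection of the Y-linked transcript Eif2s3y as a covariate, a skeletal muscle score as a covariate, both, and the tumours with or without Eif2s3y alone. A list of hair follicle keratins and a list of immediate early genes that respond to handling were also added then, as was a limma test of whether the difference between tumour types depends on Eif2s3y. Figures were drawn with matplotlib 3.10.9.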

Results

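Transcripts were measured in 12 oral tumours from mice, 6 labelled KHR and 6 labelled KHR-NICD. The tumours came from first-generation crosses of FVB and C57BL/6 mice and had grown for 21 days. The labels do not spell out KHR. NICD is the usual abbreviation for the Notch intracellular domain, the part of a Notch receptor that enters the nucleus and switches on target genes. The labels call the tumours of a group biological replicates without saying whether each came from its own animal, so p-values measure the spread between these samples. Between 43.6% and 48.1% of probes were detected per array, median signals ran from 140 to 178, and the mean number of beads per probe from 33.0 to 37.4. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.125.

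The tumours differed most along a line that did not follow the tumour type. Eif2s3y, a gene of the Y chromosome chosen like Xist after its values were seen, was detected in KHR tumours 4, 5 and 6 and in KHR-NICD tumours 1 and 4, at log2 values of 8.18 or above. In the other 7 tumours it was not detected and lay at 4.92 or below. Xist, the RNA of the silenced X chromosome, showed the opposite order, at 6.62 or above in those 7 tumours and at 5.11 or below in the 5 with Eif2s3y. The first principal component carried 40.2% of the variance and separated the same tumours, with scores of 15.5 or above where Eif2s3y was detected and -0.94 or below where it was not. Skeletal muscle genes, Ryr1 among them, had a mean log2 value of 9.23 ± 0.83 (SD, n = 7) in the tumours without Eif2s3y. In those with it the mean was 7.63 ± 0.61 (SD, n = 5), with an exact permutation p = 0.00758. Actn3, a dim member of that list, hardly differed between the 2 sets. Hair follicle keratins, a list chosen after seeing the data, stood at 8.19 ± 0.75 (SD, n = 7) and 6.74 ± 0.42 (SD, n = 5), with an exact permutation p = 0.00631. Muscle and hair keratin levels thus moved with Eif2s3y, which was present in 3 of 6 KHR and 2 of 6 KHR-NICD tumours.

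**Figure D1:**
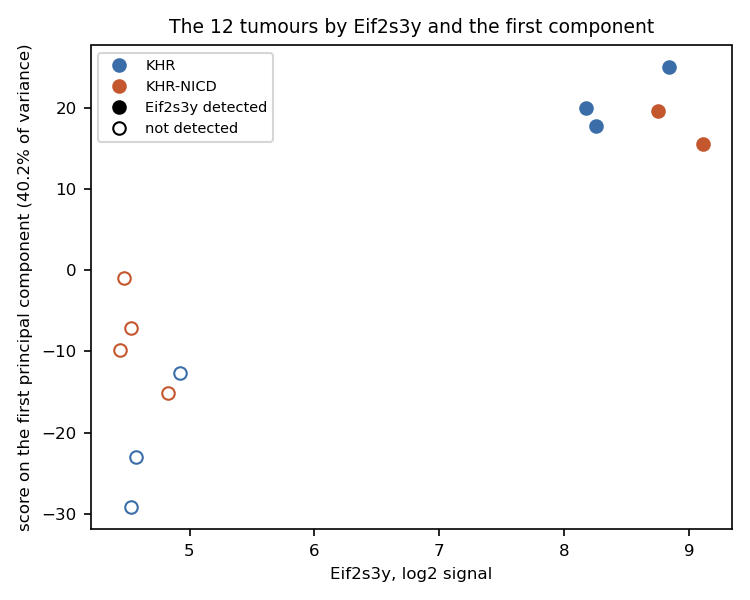
Each point is 1 tumour, placed by the log2 signal of Eif2s3y and by its score on the first principal component, which carries 40.2% of the variance. The 5 tumours with Eif2s3y detected, of both tumour types, lie at 15.5 or above on the component, and the other 7 at -0.94 or below.

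The comparison of KHR-NICD with KHR tumours asks which transcripts differ in tumours labelled with NICD. Among called genes detected in both groups, Hs3st1, Dusp4, Klk14 and Phlda1 fell most. Dusp4, a phosphatase that switches off MAP kinases, fell from 8.89 ± 0.34 to 7.75 ± 0.26 (SD, n = 6 each), a difference of -1.14 with a standard error of 0.16 (limma adjusted p = 0.0208). Phlda1, a pleckstrin homology protein induced by growth factors, fell from 11.60 ± 0.13 to 10.57 ± 0.37 (SD, n = 6 each; limma adjusted p = 0.0208). Hs3st1, a heparan sulphate sulphotransferase, showed the largest fall among called genes detected in both groups. It went from 10.45 ± 0.50 to 8.98 ± 0.36 (SD, n = 6 each), which is 2.76-fold (limma adjusted p = 0.0258). Every KHR-NICD tumour lay below every KHR tumour for these 3 genes. Klk14, a kallikrein-related serine protease, was 2.19-fold lower, with 5 of 6 KHR-NICD tumours below all KHR tumours (limma adjusted p = 0.0392).

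In all, limma called 17 of 8420 genes, 8 higher and 9 lower in KHR-NICD tumours, and for each of them but Klk14 all 6 KHR-NICD tumours lay beyond every KHR tumour. Camsap2, which binds the minus ends of microtubules, had the smallest adjusted p, 0.00429 by limma. It was detected in 6 of 6 KHR tumours and was not above background in any KHR-NICD tumour, so its level was at least 1.52-fold lower there. The other genes that fell were Rbm15, part of the complex that methylates RNA, Slco2a1, a prostaglandin transporter, Arc, an immediate early gene, and Anxa11, an annexin, with log2 differences of -0.80, -0.69, -0.61 and -0.50. Among genes that rose, Slco1a5, an organic anion transporter, gained 0.78 with a standard error of 0.12, and Cmas, which activates sialic acid, gained 0.75 with a standard error of 0.13. Oser1 gained 0.70, Spc25, a kinetochore protein, 0.67, Ccdc77 0.59, Pyroxd1, an oxidoreductase, 0.50 and Tpgs1, a subunit of a tubulin-modifying enzyme, 0.45. Chl1, a cell adhesion protein, was not above background in any KHR tumour and was detected in 6 of 6 KHR-NICD tumours, at least 1.34-fold higher, while its 3 other probes were detected on 0 arrays.

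**Figure D2:**
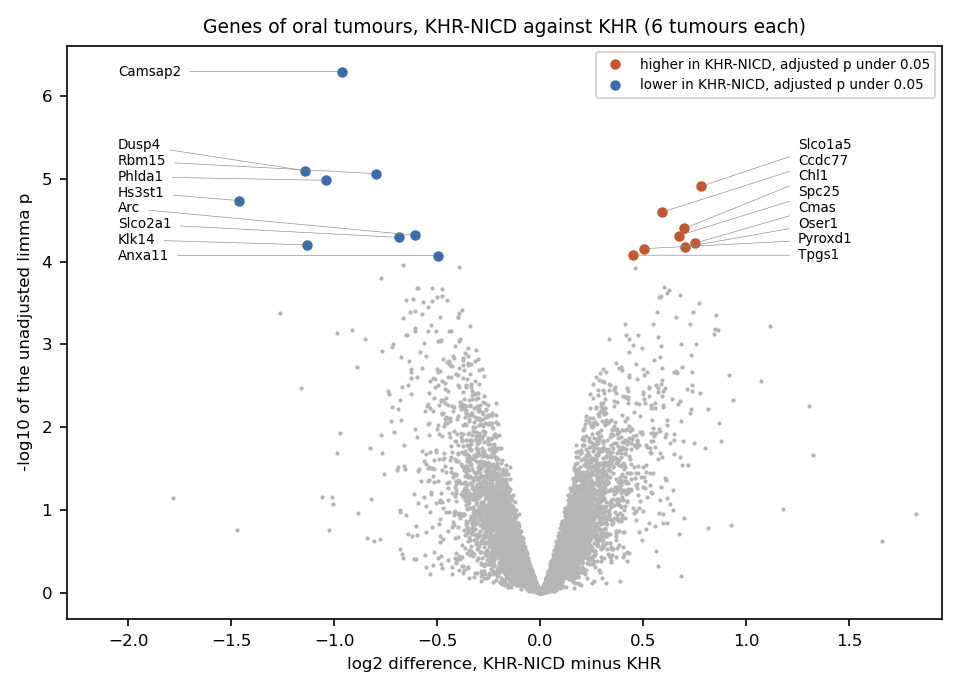
Each point is 1 of 8420 genes, with the log2 difference (KHR-NICD minus KHR) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Coloured and named points are the 17 genes past an adjusted p of 0.05, 8 higher and 9 lower in KHR-NICD tumours.

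At an unadjusted p under 0.05, limma gave 1173 genes, 575 higher and 598 lower, where chance would give 421 on average. The groups did not overlap for 132 genes, 1.57% of those tested, where chance gives 0.216% on average. The spread of these 2 chance values, which grows when genes move together, was not estimated. With detection of Eif2s3y as a covariate, chosen after seeing the data, limma called 216 genes, 91 higher and 125 lower, including all 17. Within the 7 tumours without Eif2s3y (3 KHR and 4 KHR-NICD), limma called 1 gene, Prl2c3, named here after its values were seen. Within the 5 tumours with it (3 KHR and 2 KHR-NICD), limma called 0 genes, with 2144 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0550. All 17 genes had the pooled direction in both sets, which are the samples they were picked on. For each of them but Klk14 that outcome was fixed, since the groups did not overlap. KHR tumours of the first set are replicates 1 to 3 and those of the second 4 to 6, so the sets differ in replicate number too. The count was 24 without KHR tumour 1, 3, 1, 11, 9 and 4 without KHR tumours 2, 3, 4, 5 and 6, and 10, 2, 6, 9, 12 and 4 without KHR-NICD tumours 1 to 6, with Camsap2 called each time. Median centring in place of quantile normalization gave 54 genes, 5 higher and 49 lower. It also moved the median log2 difference over all genes to -0.08, from 0.005 with quantile normalization.

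Camera called 4 of 26 gene lists, 1 higher and 3 lower in KHR-NICD tumours, of which 1 held with an estimated correlation. By the exact permutation test of list scores 0 lists passed adjustment and 4 had an unadjusted p under 0.05, while limma's fry called 1 list in a direction and 5 in either direction. The list of RAS-MAPK feedback and immediate early genes, which record signalling from growth factor receptors through RAS, was lower in KHR-NICD tumours. Of its 12 measured members, 0 rose, 2 fell (Dusp4 and Phlda1) and 10 did not pass, and adjusted over the list alone 0 rose and 5 fell. Values of members that did not pass over all genes were -0.67 for Epha2, a receptor kinase, -0.57 for Hbegf, a ligand of the EGF receptor, and, chosen after their values were seen, -0.68 for Dusp6, a MAP kinase phosphatase, and +0.13 for Etv4. In all, 11 of 12 members had a negative difference. The median difference was -0.55, and camera gave an adjusted p = 1.83e-06, with adjusted p = 0.00698 with an estimated correlation. The mean of the list per tumour was 10.03 ± 0.09 in KHR and 9.57 ± 0.11 in KHR-NICD (SD, n = 6 each), with no overlap between the groups and an exact permutation p = 0.0022, the smallest that 6 against 6 can give and 0.0563 after adjustment, which did not pass. The mean difference of the list was -0.39 in the 7 tumours without Eif2s3y (camera adjusted p = 0.000205) and -0.51 in the 5 with it (camera adjusted p = 0.00712), calls lost at adjusted p = 0.245 and adjusted p = 0.504 with an estimated correlation, with which no list passed in either set. The direction of the RAS-MAPK list in both sets was fixed, since the list scores of the groups did not overlap. Beside this list, without Eif2s3y, stood muscle at -0.89, macrophage and dendritic cell markers at -0.33 and interferon response genes at -0.41. With Eif2s3y, fibroblast markers stood at +0.59 and macrophage and dendritic cell markers at +0.42.

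**Figure D3:**
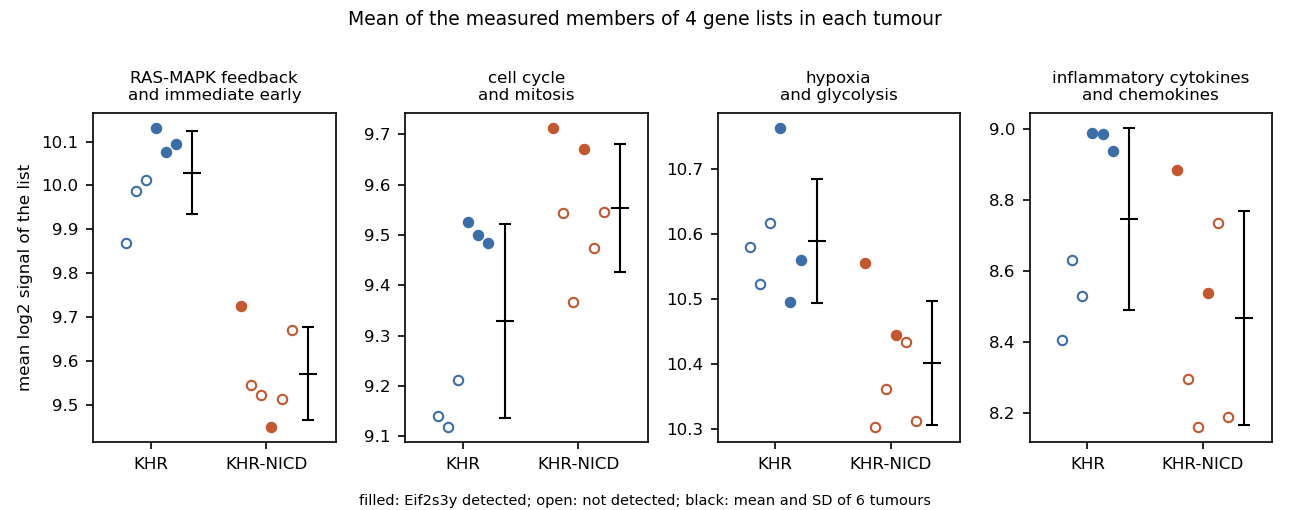
Each point is the mean log2 signal of a gene list in 1 tumour, filled where Eif2s3y was detected and open where it was not, and the black marks are the mean and SD of 6 tumours. In the RAS-MAPK panel the highest KHR-NICD tumour, at 9.73, lies below the lowest KHR tumour, at 9.87, while the groups overlap in the other 3 panels.

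Notch target genes showed no rise that passed the test in the tumours labelled NICD. Of the 7 measured members of the Notch target list 0 rose, 0 fell and 7 did not pass, and adjusted over the list alone 0 rose and 1 fell, Hey1. Hes1, a repressor that Notch induces directly, stood at 9.64 ± 0.14 in KHR and 9.64 ± 0.20 in KHR-NICD tumours (SD, n = 6 each), with a 95% interval of the difference from -0.23 to 0.23. Hey1, a repressor of the same family, had a difference of -0.65 with a standard error of 0.15 (limma adjusted p = 0.0855), with all 6 KHR-NICD tumours below every KHR tumour and detection in 4 of those 6. Nrarp, a Notch feedback inhibitor, stood at -0.14, Notch3 at -0.13, Ptcra at +0.03, Ccnd1 at +0.21 and Gata3, chosen after its value was seen, at +0.02. Hes5, Hey2, Heyl, Dtx1 and Hes7 were detected on 0 arrays. Il2ra, Myc, Dll1 and Jag1, the rest of the 16 genes listed, did not pass the detection filter. Notch1 itself had a difference of +0.31 with a standard error of 0.15 (limma adjusted p = 0.368), and whether its probe reads the NICD transcript is not known. The list had a median of 0.00 and a mean of -0.09, and camera gave an adjusted p = 0.386. Notch receptors, ligands and processing enzymes had a median of -0.03 over 14 measured genes, of which 0 rose and 0 fell (camera adjusted p = 0.503), and Ncstn, a subunit of the gamma-secretase that frees NICD, stood at -0.44 (limma adjusted p = 0.186).

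**Figure D4:**
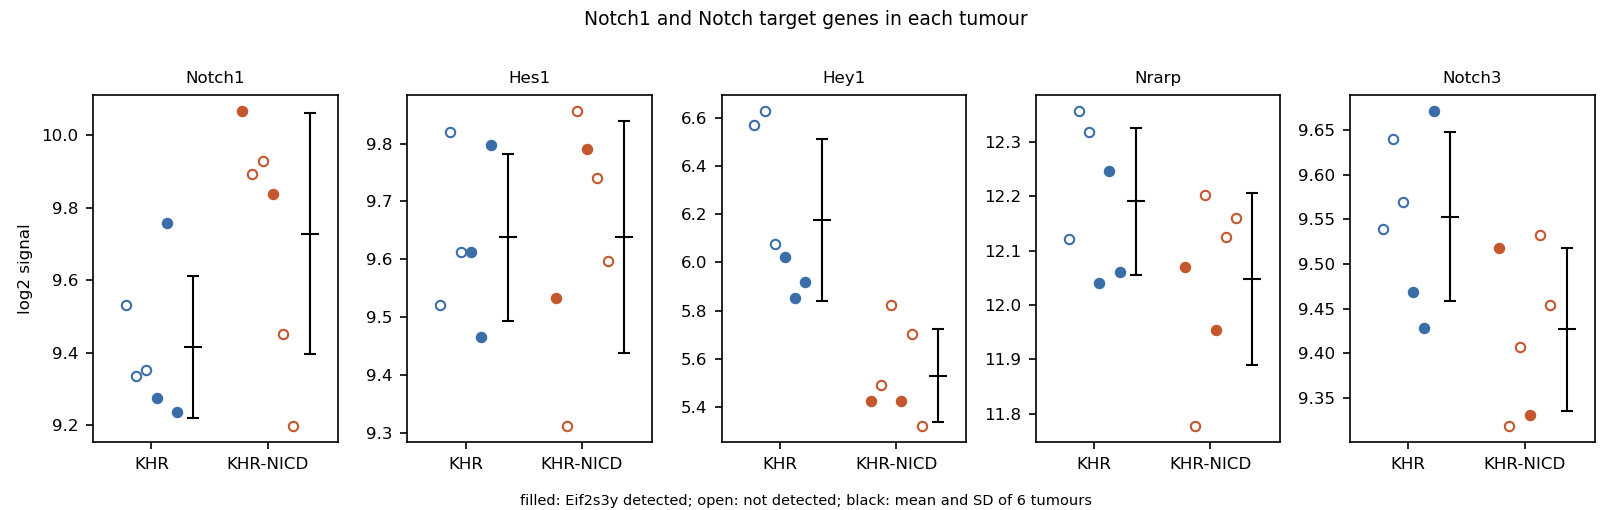
Each point is the log2 signal of a Notch gene in 1 tumour, filled where Eif2s3y was detected, with the mean and SD of 6 tumours per group in black. Hes1 has the same mean of 9.64 in both groups, and the Hey1 values of KHR-NICD tumours lie below those of KHR tumours.

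The cell cycle list was higher in KHR-NICD tumours by camera (adjusted p = 0.00213), a call lost at adjusted p = 0.587 with an estimated correlation. Of its 22 measured members 0 rose, 0 fell and 22 did not pass over all genes, and adjusted over the list alone 6 rose and 1 fell. Nusap1 and Tpx2, which organise the mitotic spindle, stood at +0.43 and +0.59, Birc5 (survivin) at +0.43 and Pcna, the replication clamp detected in 1 KHR and 5 KHR-NICD tumours, at +0.57, while Ccne1, chosen after its value was seen, stood at -0.26. The median was +0.19, and the list scores of 9.33 ± 0.19 in KHR and 9.55 ± 0.13 in KHR-NICD tumours (SD, n = 6 each) gave an exact permutation p = 0.0455, or 0.295 after adjustment. Within KHR, the 3 tumours with Eif2s3y had scores from 9.48 to 9.53 and the 3 without it from 9.12 to 9.21. The list's mean difference was +0.33 in the 7 tumours without Eif2s3y (camera adjusted p = 2.14e-05), where muscle genes stood at -0.89 (camera adjusted p = 2.14e-05), and +0.19 in the 5 with it (camera adjusted p = 0.109). Without Eif2s3y both calls were lost, at adjusted p = 0.245 for cell cycle and adjusted p = 0.627 for muscle with an estimated correlation.

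Genes of hypoxia and glycolysis were lower by camera (adjusted p = 0.0022), again with the call lost at adjusted p = 0.376 with an estimated correlation. Of 17 measured members 0 rose, 0 fell and 17 did not pass, and adjusted over the list alone 1 rose and 3 fell. Ndrg1, a hypoxia-induced gene, stood at -0.85, Slc2a1, the glucose transporter GLUT1, at -0.44 and the glycolytic enzyme Aldoa at -0.32, whereas Pgk1, detected in 1 KHR and 5 KHR-NICD tumours, stood at +0.48. The list scores of 10.59 ± 0.10 and 10.40 ± 0.10 (SD, n = 6 each) gave an exact permutation p = 0.00649, or 0.0844 after adjustment. Within tumours without Eif2s3y the mean difference was -0.22 (camera adjusted p = 0.00263), beside -0.89 for muscle genes, -0.33 for macrophage and dendritic cell markers (camera adjusted p = 0.000565) and -0.41 for interferon response genes (camera adjusted p = 0.00448). These calls were lost, at adjusted p = 0.245, adjusted p = 0.608 and adjusted p = 0.27 for hypoxia, macrophages and interferon with an estimated correlation. Within tumours with it the mean difference was -0.11 (camera adjusted p = 0.575).

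Inflammatory cytokines and chemokines were lower by camera (adjusted p = 0.00307), a call lost at adjusted p = 0.376 with an estimated correlation. Of 14 measured members 0 rose, 0 fell and 14 did not pass, and adjusted over the list alone 1 rose and 4 fell. The neutrophil attractant Cxcl1 stood at -0.77, the alarmin Il33 at -0.60, Il1rn, which blocks the interleukin-1 receptor, at -0.53, and Il1f6, an interleukin-1 family cytokine, at +0.66. The list scores of 8.75 ± 0.26 and 8.47 ± 0.30 (SD, n = 6 each) gave an exact permutation p = 0.119, or 0.442 after adjustment. Within tumours without Eif2s3y the mean difference was -0.18 (camera adjusted p = 0.0495, but adjusted p = 0.608 with an estimated correlation) and within those with it -0.26 (camera adjusted p = 0.0869), where macrophage and dendritic cell markers stood at -0.33 and +0.42. The muscle and hair keratin levels described above also varied within both groups, and the skeletal muscle list had a median difference of -0.09 between the groups (camera adjusted p = 0.566).

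Keratinocyte lists did not pass between the tumour types. Basal keratinocyte genes had a median of -0.09 (camera adjusted p = 0.255), with Cdh3, the P-cadherin gene, at -0.48 (limma adjusted p = 0.0656), the 1 fall adjusted over the list alone, and Trp63, the basal transcription factor, at -0.15. Suprabasal keratins and desmosomal genes had a median of -0.05 and a mean of +0.03, with the test pointing down (camera adjusted p = 0.566), with Dsg3 at -0.68 and Grhl3 at -0.46, and adjusted over the list alone 2 fell. Cornified envelope genes had a median of -0.02 and a mean of +0.01, with the test pointing down (camera adjusted p = 0.566), with Lce1f at +0.44 and Sbsn at -0.30.

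Markers of other cells in the tumours did not pass either. Fibroblast markers had a median of +0.22 (camera adjusted p = 0.255), with Lum at +0.80 and Col3a1 at +0.55. Endothelial markers had a median of -0.09 (camera adjusted p = 0.566), with 8 of 11 members negative. Among them Flt1 stood at -0.20, Tek at -0.21 and Robo4 at -0.25, while Vwf stood at +0.58. Pericyte and smooth muscle markers had a median of -0.11 (camera adjusted p = 0.393). Macrophage and dendritic cell markers had a median of -0.03 (camera adjusted p = 0.949), neutrophil markers -0.18 (camera adjusted p = 0.393), mast cell markers -0.09 (camera adjusted p = 0.946), and Schwann cell and neuron markers -0.11 (camera adjusted p = 0.402). T and NK cell, B and plasma cell, salivary gland, adipocyte, melanocyte, red blood cell and Hedgehog lists had fewer than 5 measured members and were not tested.

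Among the other pathway lists, with 0 members called in each, the epithelial to mesenchymal transition list had a median of -0.07 (camera adjusted p = 0.255), with Zeb2 at +0.51 and Itga5 at -0.46. Metalloproteinase and proteolysis genes had a median of -0.16 (camera adjusted p = 0.386), and interferon response genes one of -0.14 (camera adjusted p = 0.566). The p53 targets had a median of -0.02 (camera adjusted p = 0.503), with Sesn2 at -0.72, the 1 fall adjusted over the list alone, and Cdkn1a at -0.22. Canonical Wnt targets had a median of +0.01 and a mean of -0.03 (camera adjusted p = 0.97), YAP and TEAD targets +0.01 and -0.03 (camera adjusted p = 0.949), and TGF-beta and BMP targets -0.07 and -0.01 (camera adjusted p = 0.646), with the test pointing down for all 3 lists. NRF2 and xenobiotic defence genes had a median of +0.13 (camera adjusted p = 0.566) and ribosomal protein genes one of +0.05 (camera adjusted p = 0.386).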

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

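The tests of explanations in this part were chosen after the results were seen, except the counts of splits for called genes and called lists, and so were the tests of beads and of dependence on Eif2s3y.

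The lower RAS-MAPK feedback list was weighed first, as the list with the smallest p of 26, and whether chance can be excluded is undecided. Of 100 splits of the 12 tumours, 1, the real one, gave this list an adjusted p as small (smallest other 1.88e-05), but 17 gave some list one as small at the preset correlation, the 16 others for skeletal muscle (13, down to 6.44e-24) or macrophages (3), whose estimated correlations of 0.878 and 0.420 exceed the 0.00682 of this list, and with an estimated correlation 1 of 100, the real one, did (smallest other 0.0225). Unequal numbers of tumours with Eif2s3y and different amounts of muscle are argued against as its cause, since the mean difference of -0.46 (standard error 0.06) stayed at -0.44 with Eif2s3y and at -0.46 with the muscle score as a covariate. Handling of the tissue stays open, since 17 other immediate early genes missed the mean of -0.23 that handling was set to need, at -0.14 (standard error 0.05), but had a median of -0.21 with an SD of 0.27 over members, 12 lower and 5 higher. Exchanged labels stay open too, since the 0 KHR-NICD tumours above the lowest KHR tumour would be 0 under exchange as well, and no biological explanation was tested.

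The first principal component was weighed next, since it follows Eif2s3y and not the tumour type. Deposit order as the only cause is argued against, since in KHR-NICD replicates 4 to 6 differed from 1 to 3 by 1.04. In KHR they differed by 42.5, and there order cannot be told apart from Eif2s3y, detected in tumours 4, 5 and 6 alone. The arrays did split by order in both groups. Their highest signal was 24556 or above in replicates 1 to 3 and 23829 or below in 4 to 6. Detected probes numbered 11771 or more and 11727 or fewer. Only the replicate block took this order into account. For muscle and hair follicle tissue the tests disagree. With both tissue scores as covariates, 1 of 1566 genes associated with Eif2s3y stayed called, as tissue content would give, but in a test added once that count was known the median ratio of the differences was 0.82, as it would not, and the scores overlap with Eif2s3y (variance inflation 5.14). Tissue content and Eif2s3y therefore cannot be told apart in these 12 tumours. The mean number of beads per probe separated the same tumours, at 36.31 or above with Eif2s3y and 36.14 or below without it. Whether a difference between arrays plays a part in the component was not tested. The 5 tumours with Eif2s3y at 8.18 or above had Xist at 5.11 or below. The other 7 had Eif2s3y at 4.92 or below and Xist at 6.62 or above. Male and female tissue would give this split, though the labels do not give the sex of the animals. A role of sex beside tissue content was not tested.

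The lack of a rise in Notch targets was weighed last. Exchanged group labels stay open, since the 1 of 26 lists that separated the groups would do so under exchange too, and Hey1, lower in all 6 KHR-NICD tumours, would then be higher. Upper 95% bounds lay under 1.5-fold for Hes1, Hey1, Nrarp and Notch3, 4 targets picked after their values were seen. Such bounds alone cannot exclude a dim probe, whose differences can be small for that reason. Probes too dim to show a rise are argued against for Hes1, Nrarp and Notch3, detected on every array with group means of 9.4 or above. Hey1 stays open, since its means of 6.18 and 5.53, with detection in 4 of 6 KHR-NICD tumours, lie nearer background. Of the 3 other measured members, 2 (Gata3 and Ccnd1) had upper bounds above that, and Hes5, Hey2, Heyl, Dtx1 and Hes7 were detected on 0 arrays, so a rise in these is not excluded. Nor is a rise excluded in Il2ra, Myc, Dll1 and Jag1, which the detection filter left out. Whether the Notch1 probe reads the NICD transcript is not known, so the level of NICD stays open.

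For the count of called genes, 2 of 100 splits gave as many as the real 17, the real one included. So many calls were thus uncommon among the splits drawn, which argues against chance without excluding it. The highest other split gave 46 genes, and it put all 5 tumours with Eif2s3y on 1 side, which points to a structure of the samples. With Eif2s3y as a covariate, 1 of 100 splits that kept its numbers per group gave as many as the real 216, and the highest other gave 2. For the count of called lists, 39 of 100 splits gave as many as the real 4, with up to 9 in another split, so chance cannot be excluded for that count.

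Samples far from the rest of their group were found in 5 of 104 groups tested, where chance gives 5.2. The suprabasal list stood at 11.24 in KHR-NICD tumour 4, below the others, and the YAP and TEAD list at 7.97 in KHR tumour 1, above the others. Klk14 stood at 11.33 in KHR-NICD tumour 6, Oser1 at 7.92 in KHR-NICD tumour 1, and Spc25 at 7.54 in KHR-NICD tumour 5. The mean number of beads per probe, which entered no comparison, was higher by 1.92 in the tumours with Eif2s3y than in those without, with an exact permutation p = 0.00505. The difference between tumour types itself differed between tumours with and without Eif2s3y for 24 genes (limma interaction, adjusted p under 0.05). At an unadjusted p under 0.05 that test gave 1505, where chance gives 421 on average, with a spread that was not estimated. KHR tumours without Eif2s3y are replicates 1 to 3 and those with it 4 to 6. Dependence on Eif2s3y and on deposit order therefore cannot be fully told apart.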

How the results depend on the processing

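Alternatives with Eif2s3y or muscle were chosen after seeing the data. For each change below the cause was not tested, except that stricter thresholds lower counts by construction. Against 17 called genes (8 higher, 9 lower), there were 28 (7 and 21) without background correction, 54 (5 and 49) with median centring, 31 with 19 lower under a trended robust variance, 125 (50 and 75) with array weights, and 21 with 15 lower under normexp with offset 50. With median centring the median difference over all genes was -0.08, against 0.005 in the main fit. A difference of at least 1 left 4 (0 higher), and adjusted p under 0.01 left 1, Camsap2. The counts were 216 (91 and 125) with Eif2s3y as a covariate, 109 (35 and 74) with muscle, 173 (64 and 109) with both, 1 (1 and 0) in tumours without Eif2s3y and 0 in those with it. The deposited values (21), probe filters (15 to 17) and probe means (22) stayed within 1.5 times.

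Leaving out 1 tumour gave 1 to 24 genes, 0 to 11 higher and 1 to 13 lower. It gave 3 without KHR 2, 1 without KHR 3, 11 without KHR 4, 9 without KHR 5 and 4 without KHR 6, and 10, 2, 6, 9 and 4 without KHR-NICD 1, 2, 3, 4 and 6. The replicate block left 1 gene (0 higher, 1 lower), Camsap2. Pairing was judged on each gene's deviation from its group mean. These deviations correlated from -0.22 to 0.45 between same-number tumours, with 2 of 6 pairs over 0.1. By them, 1 of 6 KHR and 0 of 6 KHR-NICD tumours correlated best with their own number, so the numbers were not taken as pairs.

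Camera's 4 lists became 1 with an estimated correlation (adjusted p = 0.587 for cell cycle, 0.376 for inflammation and 0.376 for hypoxia) and 1 by fry's directional test (0.244, 0.0779 and 0.0557), while fry in either direction added suprabasal keratins at 0.0326. Array weights gave 0.158 for cell cycle and 0.0178 for basal keratinocytes, and median centring 0.0276 for fibroblasts. Tumours without Eif2s3y gave 7 lists, with interferon at 0.00448, muscle at 2.14e-05 and macrophages at 0.000565, all lower. With an estimated correlation no list passed in either set. Tumours with Eif2s3y gave cell cycle 0.109, inflammation 0.0869, hypoxia 0.575, fibroblasts 0.00382 (higher), and macrophages reversed to higher at 0.000716. Leaving out 1 tumour gave 1.88e-07 to 1.50e-05 for the RAS-MAPK list, 0.0389 to 0.395 for basal keratinocytes and 0.0284 to 0.411 for fibroblasts. List scores passing adjustment numbered 0, but 2 under the stricter filter, and 0 to 2 when leaving out 1 tumour. No named gene reversed its direction past the threshold. A slide block was not run, since the files used here name no slide. Signal over background limits Camsap2 and Chl1 to bounds.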

Other observations

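The fits in this part were chosen after seeing the data. With Eif2s3y as a covariate, 5 members of the RAS-MAPK list fell (Dusp6, Dusp4, Phlda1, Epha2 and Hbegf), with Dusp6 at -0.80 and a standard error of 0.09 (limma adjusted p = 0.00339). In that fit 5 cell cycle genes rose (Cdk1, Birc5, Kif11, Nusap1 and Cdca8), with Cdk1, the kinase of mitotic entry, at +0.49 and a standard error of 0.07 (limma adjusted p = 0.00867). The inflammatory list had 4 falls (Cxcl1, Il1rn, Il33 and Il23a), and the hypoxia list 1 rise (Pgk1) and 2 falls (Ndrg1 and Aldoa). Single members of other lists that did not pass also fell in that fit, Cdh3 by 0.44, Dsg3 by 0.60, Ncstn by 0.50 and Sesn2 by 0.76 (limma adjusted p from 0.0205 to 0.0374), and none of these 4 passed without the covariate. Hey1 fell by 0.70 with a standard error of 0.12 (limma adjusted p = 0.0239) in that fit, against a limma adjusted p = 0.0855 without the covariate, and the Notch target list did not pass with it (camera adjusted p = 0.43). Camera gave the RAS-MAPK list an adjusted p = 0.0304 with an estimated correlation in that fit, and the cell cycle list an adjusted p = 0.131 with an estimated correlation.

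Outside the fixed lists and chosen after their values were seen, the same fit put Cyp2b10 at -1.22, Nppb at -1.15, the hair follicle keratin Krt73 at -1.12, Angptl4 at -0.99 and the chemokine Cxcl12 at -0.98, and Spink7 at +1.13. Of salivary gland markers, a list with too few measured members for a test, Aqp5, a water channel, rose by 0.84 and Ptn, a growth factor, by 0.77 in that fit, while the other 2 measured, Lpo at -0.87 and Slc12a2 at +0.19, did not pass.

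Macrophage and dendritic cell markers differed by -0.33 between tumour types in the 7 tumours without Eif2s3y and by +0.42 in the 5 with it. A permutation test over all 350 regroupings of the tumours within the 2 sets gave p = 0.00571 and 0.149 after adjustment over 26 lists, so it did not pass. Such regroupings assume no difference between tumour types in either set, so the test does not address equal differences alone. Among the 24 genes whose difference did pass the interaction test, named after their values were seen, Prl2c3 differed by 2.50 without Eif2s3y and by -1.41 with it (limma adjusted p = 0.0133), and Apoe, an apolipoprotein of macrophages and other cells, by -0.48 and 1.23 (limma adjusted p = 0.03). The set with Eif2s3y holds 2 KHR-NICD tumours. Its KHR tumours are replicates 4 to 6 and those of the other set 1 to 3, so Eif2s3y and deposit order cannot be fully told apart.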
